A study of Mus musculus with 8 samples.

How the data were processed

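The data are 1-color Agilent mouse arrays, 1 for each of 8 mice, hybridized with polyA RNA of B splenocytes. Per the labels, 0.5 µg of RNA was used per array, extracted by the Chomczynski method, labelled with Cy3 and processed with the Agilent low RNA input protocol. Groups were taken from the sample labels, which put 4 mice in the wild type group and 4 in the lymphoma group. The slide and position of each array were read from the array identifiers in the labels, and each slide held 2 arrays of each group.

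The authors deposited a table of log2 intensities for 45220 features on the 8 arrays. The scanner, the background correction and the normalization behind it are not given in the sources used here. Checked on the values, 2 to the power of each value runs in steps of a constant size within an array, from 0.798 to 1.25 between arrays, which held within 5% of a step for at least 99.97% of the distinct levels of each array. Each array therefore was multiplied by a factor of its own before the logarithm. The medians were 7.11, 7.26, 7.12 and 7.12 for wild type 1 to 4 and 7.04, 7.10, 7.07 and 7.09 for lymphoma 1 to 4. Values were not centered per feature, and the scale factors remain unknown. The table names features by number only, so that spots carrying the same probe could not be averaged.

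Features were named through the platform annotation, which listed 33709 of the 45220 features with a gene. Of these, 33653 had 1 gene symbol and 56 had several and were not named. The other 11511, control spots among them, were left out of the main fit. Gene identifiers of 33517 listed features matched a table of RefSeq genes of assembly GRCm38.p6, and 0 symbols changed. That table was used for names only. A gene was represented by its feature with the highest mean over all 8 arrays, which gave 19087 genes. Among called genes with several features, 180 in number, 85.4% of the other features had the same direction, and 1 gene had another feature called the opposite way.

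Before the data were examined it was fixed that the deposited scaling would be kept if the 75th percentiles of the arrays lay within 0.1 log2 of one another. They differed by 0.215, so each array was set to its 75th percentile over the listed features. The limma package (version 3.58.1, R version 4.3.3) was then used with lmFit and eBayes and the group as the only term, two-sided, with Benjamini-Hochberg adjustment over all 33709 features. No filter on dim features was applied. A call is an adjusted p under 0.05, and all single-gene p values in the text come from limma. Apart from the genotype and strain given under Results, nothing in the labels says more of the mice than that they are separate. The p values set the difference between the groups against the spread between mice within them.

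No flags for background or saturation come with the table. After the values were seen, the background bound of an array was set at the 95th percentile of its 1113 features for olfactory and vomeronasal receptors, which lay between 7.17 and 7.45 after scaling. A feature was taken as near the ceiling where its intensity was at least 80% of the highest on the array. A gene at background on all arrays of a group is given as at least N-fold, where N sets the brighter group's mean against the mean of, per array, the higher of the bound and the measured value. Among the 398 called genes 26 were at background in 1 group and 372 were measured in both.

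Before the data were examined, 35 gene lists were fixed, and each was tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry stand beside it. Counts of list members are given over all features tested and adjusted over the list alone. Lists share members: 12 of the 37 mature B cell genes and 8 of the 14 follicular genes are also in another list. The named genes follow a rule fixed at the same time. They are the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, leaving out predicted transcripts and variable segments of antigen receptors. To these come a fixed set (Myc, Cdk4, Ccnd1, Ccnd2, Ccnd3, Cdkn2a, Trp53, Bcl2, Cd5, Sox11 and Mki67), and for each list up to 3 called members with the largest change and 1 in the opposite direction. For a list with no called member, the member with the largest difference is given with its p, an addition made after the values were seen. Trp53 is not analysed here, and 1 further gene of the fixed set is not reported here.

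The spread between mice was compared by an exact permutation test over the 70 assignments of 8 distances. Differences between slides were tested in limma with the group as a second term. Alternatives were quantile normalization, the deposited scaling, scaling to the median, leaving out the dimmer 50% of features, a floor at the 5th percentile of all values, eBayes with trend and robust settings, array weights, the slide or the replicate number as a block, each slide alone, a plain t-test on the same values, the mean of all features of a gene, and leaving out each array in turn. Features of the whole table and the brightest feature away from the ceiling were added after the data were seen.

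The fit was tested on simulated data with the means of the real 33709 features and their variances as moderated by eBayes. In each of 5 draws 200 features with a mean above 8 were changed. Moderated variances differ less between features than measured ones, so recovery in the real data may be lower. With all 8 arrays, 0.1% of 2-fold changes, 94.0% of 4-fold changes and 99.4% of 8-fold changes were recovered in the comparison of lymphoma with wild type. On average 12.6 unchanged features were called beside the 4-fold changes. Without wild type 1, 94.3% of 4-fold changes were recovered. In a draw with the interferon response list alone shifted by -1 log2, camera called that list and 0 others. Features and genes were drawn independently in these simulations. The draw therefore cannot show how camera behaves where genes are correlated. Plots were drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Of the fixed list members, Ctps1, Faim3 and Cd43 were read as Ctps, Fcmr and Spn.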

Results

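Messenger RNA was profiled in B splenocytes, the B cells of the spleen, from 8 mice. Lymphoma cells came from 4 mice that combine c-myc with Cdk4 R24C, a form of the cell cycle kinase Cdk4 that INK4 inhibitors do not hold back, and the controls came from 4 wild type C57BL/6 mice. Each mouse gave 1 array labelled with Cy3, so each group has n = 4, and the number of arrays limits the precision. Slide 1 carried wild type 1 and 2 and lymphoma 1 and 2, and slide 2 carried wild type 3 and 4 and lymphoma 3 and 4. The deposited log2 intensities had medians between 7.04 and 7.26 per array. Between 50.2% and 52.9% of the features with a listed gene lay above the background bound of their array. The study asks how a broken INK4-Cdk4 checkpoint and c-myc together give rise to a lymphoma that resembles blastoid mantle cell lymphoma, and the comparison made here is lymphoma against wild type.

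The array of wild type 1 did not lie with the other controls. Across features, its mean correlation was 0.963 with the 4 lymphoma arrays and 0.941 with the other wild type arrays, while features are not independent replicates. On the first principal component, which held 36.3% of the variance, wild type 1 scored -25.0. The lymphomas scored between -52.7 and -40.6, and the other controls scored between 47.5 and 94.2. Wild type 2 stood apart on the second component, with a score of 75.04. Because of this, values without wild type 1 stand beside the main counts and lists below. That setting was planned as part of leaving out each array in turn, and its use there was chosen after the data were seen.

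**Figure D1:**
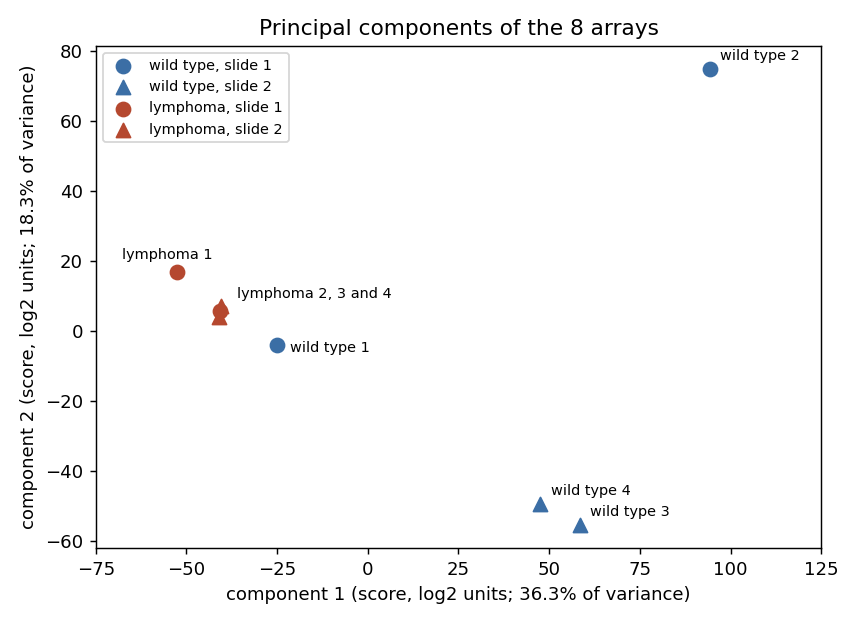
Scores of the 8 arrays on the first 2 principal components (log2 units), which held 36.3% and 18.3% of the variance. Points are arrays, colored by group and shaped by slide. Wild type 1, at -25.0 on component 1, sits nearer to the lymphomas than to the other controls.

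Genes that fell in lymphoma included Cr2 and Satb1 of mature and follicular B cells, Il21r and Lmo2 of germinal center B cells, the interferon response genes Rtp4 and Usp18 and the immediate early genes Egr1 and Jun. Mpeg1 and Fcgr1 of the macrophage marker list fell in the same comparison. It measures the RNA of the whole B splenocyte preparation and does not show which cells carried these transcripts. With the mean of its features Fcgr1 did not pass (adjusted p 0.103). Apobec2, Gng13, Ihh, Eml1 and Tppp rose from a signal at background on at least 3 of the 4 control arrays. For Ihh this holds for its brightest feature, and the mean of its 11 features differed by 0.45 (adjusted p 0.209). Fcer2a, which encodes the low-affinity IgE receptor CD23 of mature B cells, was 31.6-fold lower in lymphoma. In all, 398 of 19087 genes passed an adjusted p of 0.05 in limma, 156 higher and 242 lower in lymphoma. Of these, 154 and 235 differed by at least 2-fold. At the level of array features, 557 of 33709 passed, 221 higher and 336 lower, with 213 and 326 of them at least 2-fold. At an unadjusted p under 0.05 there were 3039 genes and 4900 features. The 4 lymphoma values lay beyond the 4 wild type values in 392 of the 398 genes. This held for 9.99% of all genes tested, where chance gives 2.86%.

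Leaving out wild type 1 raised the count to 1556 genes, 817 higher and 739 lower, and to 2317 features, 1223 higher and 1094 lower. At least 2-fold were 729 and 649 of those genes and 1079 and 947 of those features. All 398 genes passed in that fit too, in the same direction. This is no separate support, since leaving out an array that lay near the lymphomas tends to widen the differences. Leaving out any other array lowered the counts, to 235 genes without wild type 2, 82 without wild type 3, 78 without wild type 4, 119 without lymphoma 1, 181 without lymphoma 2, 122 without lymphoma 3 and 74 without lymphoma 4. Array quality weights gave 1441 genes. Within slide 2 alone 1288 genes passed. Within slide 1 alone, which holds wild type 1, limma called 0, with 1090 genes at an unadjusted p under 0.05. With the slide as a block the count was 455 genes. With the values as deposited, 417 genes passed, 116 higher and 301 lower, so the share of rises was 27.8% against 39.2% with scaled arrays. Values as deposited also gave 587 features, 158 higher and 429 lower.

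The 10 largest rises were Apobec2, Prkar2b, Tppp3, Gng13, Ihh, Zbtb32, Eml1, Nid1, Tppp and Ankrd13b. Apobec2, a member of the cytidine deaminase family, went from 7.79 ± 2.91 in wild type to 13.17 ± 0.12 in lymphoma (mean log2 intensity ± SD, n = 4), a log2 difference of 5.38 ± 1.06 (SE) with an adjusted p of 0.0315 in limma. Its wide control SD came from wild type 1, at 12.13 against a mean of 6.34 in the other controls. Prkar2b, a regulatory subunit of protein kinase A, was 20.5-fold higher, with 14.25 in wild type 1 against 9.48 in the other controls and 15.03 in lymphoma, and 46.8-fold higher without that array. With wild type 3 left out its log2 difference was 3.76 (adjusted p 0.118). Zbtb32, a zinc finger transcriptional repressor, was 14.7-fold higher (adjusted p 0.0206), and Nid1, a basement membrane protein, 14.6-fold higher (adjusted p 0.0255). Tppp3, Tppp and Eml1, whose products bind tubulin or microtubules, were 19.7-fold, 12.1-fold and 14.6-fold higher. Leaving out wild type 1 gave 36.2-fold for Tppp3, 25.9-fold for Zbtb32, 27.9-fold for Nid1 and 21.6-fold for Ankrd13b. Leaving out wild type 2 gave Tppp3 a log2 difference of 3.69 (adjusted p 0.0417). Gng13, a G protein gamma subunit, was 4.03 higher on the log2 scale. Ihh, the secreted signal Indian hedgehog, was at background in the controls and at least 10.4-fold higher in lymphoma. Ankrd13b was 11.5-fold higher. Apobec2, Gng13, Eml1 and Tppp were at background on 3 of the 4 control arrays, so their folds depend on the background level. The array above background was wild type 1 for all 4 genes, so that without it every control was at background. The nominal fold of Apobec2 was then 114 in place of 41.8 and that of Tppp 21.8, and without wild type 3 the log2 difference of Apobec2 was 4.79 (adjusted p 0.105). All 10 genes passed without wild type 1 as well, but only Gng13, Ihh and Eml1 passed whichever array was left out. With a trend and robust estimation in eBayes, Apobec2, Prkar2b, Tppp3, Zbtb32, Nid1, Tppp and Ankrd13b did not pass (adjusted p 0.0811 to 0.172). With the mean of its 11 features Ihh differed by 0.45 (adjusted p 0.209).

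The 10 largest falls were Fcer2a, Pxdc1, Cr2, Emid1, Gsn, Icosl, Prr23a3, Satb1, Myof and Rasgrp3. Fcer2a went from 13.36 ± 0.98 in wild type to 8.38 ± 0.41 in lymphoma (mean log2 intensity ± SD, n = 4), a log2 difference of -4.98 ± 0.42 (SE) with an adjusted p of 0.00246 in limma. Cr2, the complement receptor CD21, differed by -4.17 on the log2 scale, with an adjusted p of 0.00743. Icosl, the ligand of the T cell costimulator ICOS, was 12.8-fold lower, and Satb1, a chromatin organizer, 12.3-fold lower. Rasgrp3, which activates Ras downstream of the B cell receptor, was 11.5-fold lower. Gsn, the actin-severing protein gelsolin, was 13.4-fold lower, and Myof, the membrane protein myoferlin, 11.6-fold lower. Pxdc1 was 19.6-fold lower and Emid1 14.4-fold lower. Leaving out wild type 1 gave falls of 30.2-fold for Pxdc1, 28.7-fold for Cr2, 21.7-fold for Emid1, 19.5-fold for Icosl and 17.6-fold for Rasgrp3. Prr23a3 was at background in lymphoma and at least 7.95-fold lower there. Among these genes too, wild type 1 lay between the other controls and the lymphomas for Fcer2a, at 11.94 against a mean of 13.83 in the other controls, and for Cr2, at 10.69 against 13.39.

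**Figure D2:**
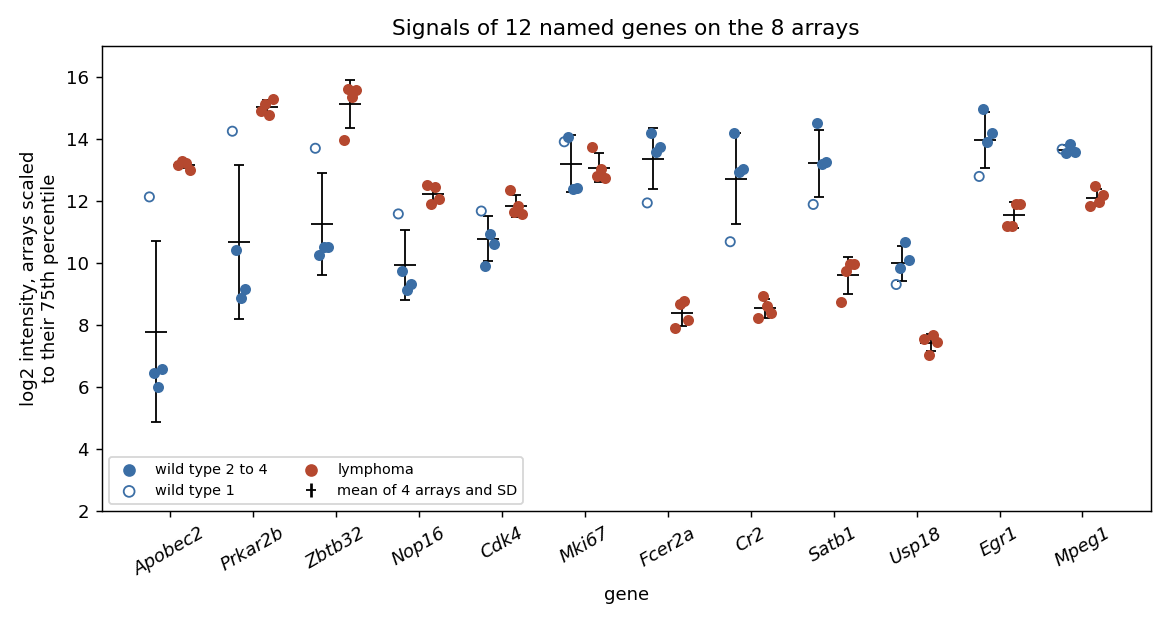
Log2 intensity, with each array scaled to its 75th percentile, of 12 named genes on the 8 arrays. Points are single arrays, the open circle is wild type 1, and bars give the mean of 4 arrays and the SD. For Apobec2 wild type 1 stands at 12.13, near the lymphoma mean of 13.17, and for Mpeg1 it stands at 13.67, within the controls.

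Of the 54 named genes past the threshold, 19 stayed past it whichever array was left out. These were Ccl3, Ccr6, Cr2, Emid1, Eml1, Fcer2a, Gng13, Gsn, Icosl, Ihh, Il21r, Lmo2, Mpeg1, Myof, Prr23a3, Pxdc1, Rtp4, Satb1 and Usp18. Leaving out wild type 2 ended 24 calls, wild type 3 ended 34, wild type 4 ended 34, lymphoma 1 ended 28, lymphoma 2 ended 22, lymphoma 3 ended 26 and lymphoma 4 ended 33. The adjusted p then reached at most 0.154. All 54 kept their direction in each of these fits. None lost its call without wild type 1, an array singled out for lying near the lymphomas. Calls also ended for 12 of the 54 with a trend and robust estimation in eBayes (adjusted p up to 0.172), 8 with the mean of all features of a gene (up to 0.326), 7 within slide 2 alone (up to 0.147), 5 with quantile normalization (up to 0.0814) and 54 within slide 1 alone. The mean of all features ended those of Fcgr1 (adjusted p 0.103), Nop16 (0.0848) and Polr1b (0.294) among others.

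Myc and Cdk4, the genes at the center of the model, gave smaller values. The brightest Myc feature differed by 0.37 ± 0.25 on the log2 scale (adjusted p 0.533), and it lay near the scanner ceiling on 4 arrays. Myc had 12 features, with differences between 0.35 and 1.61, and none passed the test. The Myc feature with the difference of 1.61 had an adjusted p of 0.106, and without wild type 1 its difference was 2.16 with an adjusted p of 3.6e-04, while it too lay near the ceiling on 4 arrays. Cdk4 was 1.06 ± 0.34 higher (adjusted p 0.166), and without wild type 1 it was 1.36 higher with an adjusted p of 0.0187. Whether a feature also reads transcripts of the introduced c-myc is not given in the sources used here. Ccnd2, which encodes cyclin D2, differed by 0.73 (adjusted p 0.385) on its brightest feature and by 1.40 (adjusted p 0.0373) on another of its 3 features. Ccnd1, encoding the cyclin D1 that human mantle cell lymphoma overexpresses, was near background at 7.41 in wild type and 7.46 in lymphoma, with an adjusted p of 0.965. Ccnd3 differed by -0.25, Cdkn2a by 0.04, Bcl2 by -0.77 and the proliferation marker Mki67 by -0.12, with adjusted p values between 0.196 for Bcl2 and 0.977 for Cdkn2a. Bcl2 had 12 features, and their differences lay between -0.77 and 0.73. Cdkn2a lay near background, at 7.20 in wild type and 7.24 in lymphoma, with 3 control and 2 lymphoma arrays under the bound. Its 10 features differed by 0.01 to 0.61, and none passed. Cd5, a surface marker of mantle cell lymphoma, differed by 0.15 (adjusted p 0.914). Sox11 was at background in both groups.

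Among MYC-linked nucleolar and ribosome biogenesis genes, 2 of 34 measured members rose and none fell. These were Nop16, a nucleolar protein, at 4.89-fold (adjusted p 0.0334), and Polr1b, a subunit of RNA polymerase I, at 2.41-fold (adjusted p 0.0406). The list held 4 rises adjusted over the list alone. The median shift of the list was 0.51 on the log2 scale, with a camera adjusted p of 1.06e-05, and an adjusted p of 0.421 with an estimated correlation. Wild type 1 was itself higher than the other controls in this list, by a median of 1.06. Without wild type 1 the count was 11 higher and 0 lower, with an adjusted p of 0.0428 with an estimated correlation. Of 29 MYC-linked metabolic and growth genes, 1 rose, Srm, the enzyme that makes spermidine, at 2.66-fold (adjusted p 0.0302). Adjusted over the list alone 1 rose, and the median was 0.38 (camera adjusted p 0.00272; adjusted p 0.49 with an estimated correlation). Wild type 1 exceeded the other controls there by a median of 0.87, and without it 7 rose. Within slide 1 alone the mean shifts of these lists were 0.44 and 0.28 (camera adjusted p 0.119 and 0.698), and within slide 2 alone they were 0.78 and 0.65 (camera adjusted p 2.54e-09 and 1.16e-05). Without wild type 4 the mean shift of the metabolic list was 0.37 (camera adjusted p 0.0608).

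By the brightest feature of each gene, no member of the cell cycle lists passed over all genes. Among 29 D cyclin, CDK and INK4/CIP regulators of G1, 1 passed adjusted over the list alone, and E2f6, a repressor of the E2F family, had the largest difference at 1.23 (adjusted p 0.0615 over all genes). The median of that list was 0.24 with a camera adjusted p of 0.189. Of 45 DNA replication genes and 44 mitosis genes none passed in either adjustment, with medians of -0.02 and 0.01 and camera adjusted p values of 0.611 and 0.514. With wild type 1 left out, the G1 list held 4 higher and 1 lower, the replication list 2 higher and 1 lower, and the mitosis list 2 higher. Tyms, which makes thymidylate, differed by 1.19 (adjusted p 0.186), and Ncaph, a condensin subunit, by -1.40 (adjusted p 0.204). The slides disagreed here. Within slide 1 alone the mean shift of the mitosis genes was -0.31 (camera adjusted p 1.0e-04), and within slide 2 alone it was 0.29 (camera adjusted p 0.0164). The replication genes gave -0.20 (camera adjusted p 0.004) within slide 1 and 0.24 (camera adjusted p 0.112) within slide 2. Among 31 DNA damage repair genes 0 passed in either adjustment, with 1 higher without wild type 1. Fancb, a Fanconi anemia gene, differed by -0.81 (adjusted p 0.357), the median was 0.10 and the camera adjusted p was 0.921.

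Of 14 follicular B cell genes measured, 7 fell and 1 rose, with a median shift of -1.27 (camera adjusted p 4.14e-07; adjusted p 0.119 with an estimated correlation). The falls were led by Fcer2a, by Satb1 and by Ccr7, a chemokine receptor for lymph node homing, which was 6.25-fold lower. Itgb7, an integrin subunit, rose 2.26-fold. Germinal center B cell genes showed 4 falls and 0 rises among 15, with a median of -0.98 (camera adjusted p 4.96e-09; adjusted p 0.119 with an estimated correlation). Il21r, the interleukin 21 receptor, was 5.91-fold lower, Lmo2, a transcriptional cofactor, 4.41-fold lower and Fas, a death receptor, 3.88-fold lower. Without wild type 1 the follicular list held 8 lower and 1 higher and the germinal center list 9 lower, with an adjusted p of 0.0239 and 0.0346 with an estimated correlation. With all 8 arrays and adjusted over the list alone, 8 fell and 1 rose among follicular genes, and 9 fell among germinal center genes. Wild type 1 was below the other controls in both lists, by medians of -1.01 and -0.63.

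Mature B cell genes showed 5 falls among 37, led by Fcer2a, Cr2 and Cd72, a B cell coreceptor that was 3.91-fold lower. Their median was -0.35 (camera adjusted p 3.32e-05; adjusted p 0.16 with an estimated correlation), with 9 lower and 1 higher adjusted over the list alone and 9 lower without wild type 1. Of 18 plasma cell genes 4 fell, with a median of -0.58 (camera adjusted p 1.95e-05; adjusted p 0.156 with an estimated correlation). Jchain, which joins polymeric antibodies, was 9.07-fold lower, Slpi, a protease inhibitor, 6.36-fold lower and Tnfrsf17, a survival receptor of plasma cells, 3.34-fold lower. Adjusted over the list alone 7 fell and 1 rose, and without wild type 1 the counts were 6 lower and 1 higher. The Jchain feature lay near the ceiling on 2 control arrays. With the brightest feature away from the ceiling Jchain differed by -2.37 on the log2 scale (adjusted p 0.22). Its call also ended with the slide as a block (0.0566), quantile normalization (0.0582), trend and robust settings in eBayes (0.14) and the mean of its features (0.0915). Of the 14 fixed members of the immunoglobulin constant region list 4 were measured. Of these 1 fell, again Jchain, which is not itself a constant region gene, so no constant region gene passed over all features. With Jchain among them, 3 fell adjusted over the list alone and also without wild type 1. The median was -1.61 (camera adjusted p 0.00272; adjusted p 0.119 with an estimated correlation), and wild type 1 was below the other controls by a median of -1.86.

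Marginal zone and B-1 B cell genes went both ways. Of 21 members 3 rose and 3 fell, and adjusted over the list alone 4 rose and 6 fell. Zbtb32 and Anxa2, a calcium-dependent membrane binding protein that was 6.98-fold higher, were among the rises, and Cr2 and Bhlhe40, a transcription factor that was 7.29-fold lower and differed by -3.45 on the log2 scale without wild type 1, among the falls. The median was 0.14, the mean -0.12 and the camera adjusted p 0.443, and without wild type 1 there were 5 higher and 6 lower. None of 20 early B lineage and pre-B cell genes passed in either adjustment, with a median of -0.09 and a camera adjusted p of 0.0568. The mean shift of this list was -0.48 within slide 1 alone (camera adjusted p 0.00152) and -0.15 within slide 2 alone (0.804). Camera also called it lower without wild type 3 (adjusted p 0.0237), wild type 4 (0.041) or lymphoma 3 (0.0039), and without the dimmer 50% of features (0.019). Rag2, a subunit of the antigen receptor recombinase, had a difference of -1.51 (adjusted p 0.235), and without wild type 1 the list held 1 lower.

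Interferon response genes gave 7 falls and 0 rises among 29, with a median of -0.99 (camera adjusted p 3.36e-13; adjusted p 0.119 with an estimated correlation). Rtp4 was 6.80-fold lower, Usp18, a protease that removes ISG15 from proteins, 5.88-fold lower and Oasl1 5.01-fold lower. Within it 18 fell and 2 rose adjusted over the list alone, and without wild type 1 the counts were 17 lower and 2 higher, with an adjusted p of 0.0239 with an estimated correlation. Immediate early genes, which cells switch on within minutes of stimulation, gave 3 falls among 22, namely Egr1 at 5.31-fold, Egr2 at 3.65-fold and Jun at 3.50-fold lower. The median was -0.91 (camera adjusted p 2.76e-06; adjusted p 0.119 with an estimated correlation). Adjusted over the list alone 13 fell and 2 rose, and without wild type 1 the counts were 12 lower and 2 higher. Myc itself belongs to this list.

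NF-kB pathway genes gave 5 falls among 23, including Ccl3, a chemokine, at 4.95-fold, Tnfaip3, a feedback inhibitor of the pathway, at 4.25-fold and Cd40, a receptor for T cell help, at 3.50-fold lower. The median was -0.59 (camera adjusted p 1.96e-06, and 0.119 with an estimated correlation), with 8 lower adjusted over the list alone and 7 lower without wild type 1. Within slide 2 alone Tnfaip3 differed by -1.39 on the log2 scale (adjusted p 0.147). BCR signalling genes gave 4 falls among 29, led by Rasgrp3, Egr1 and Cd72, with a median of -0.39 (camera adjusted p 4.73e-06; adjusted p 0.119 with an estimated correlation). In this list 8 fell adjusted over the list alone, and 7 were lower without wild type 1. MHC class II and antigen presentation genes gave 1 fall among 17, Cd40, with a median of -0.73 (camera adjusted p 1.41e-04; adjusted p 0.119 with an estimated correlation). Adjusted over the list alone 9 fell and 1 rose, and without wild type 1 the counts were 6 lower and 1 higher. Chemokine receptor, adhesion and homing genes gave 4 falls and 1 rise among 23, with a median of -0.09 and a mean of -0.56 (camera adjusted p 0.00268; adjusted p 0.119 with an estimated correlation). The receptor Ccr6 was 9.16-fold lower and S1pr3, a receptor for sphingosine-1-phosphate, 4.07-fold lower. With the mean of its features S1pr3 differed by -1.11 on the log2 scale (adjusted p 0.0786). Within the homing list 9 fell and 2 rose adjusted over the list alone, and without wild type 1 the counts were 8 lower and 2 higher. Among 16 MHC class I processing genes 1 fell, the peptide transporter Tap1 at 2.23-fold, with a median of -0.17 and a camera adjusted p of 0.15. In this list 1 fell and 1 rose adjusted over the list alone, and 1 was lower without wild type 1.

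Metabolic and stress lists did not pass with all 8 arrays in the main fit. Glycolysis genes had 0 of 20 members past the threshold and a median of 0.22 (camera adjusted p 0.165), and Slc16a1, a lactate transporter, had the difference of 1.90 (adjusted p 0.178). Oxidative phosphorylation genes had 0 of 36 and a median of 0.17 (camera adjusted p 0.194), with Atp5o, a subunit of ATP synthase, at 1.02 (adjusted p 0.377). Chaperone and heat shock genes had 0 of 20 and a median of 0.45 (camera adjusted p 0.15). Hspb1 differed by 2.25 (adjusted p 0.28), with 14.79 in lymphoma 3 and a mean of 9.79 in the other lymphomas. None of these lists had a member past the threshold adjusted over the list alone. Among 43 ribosomal protein genes 1 rose, Rpl14 at 2.21-fold, also adjusted over the list alone, with a median of 0.12 (camera adjusted p 0.0859), and 30 members lay near the ceiling on all arrays of a group. Without wild type 1 the counts were 4 higher and 1 lower for glycolysis, 5 higher for oxidative phosphorylation, 6 higher for chaperones and 2 higher for ribosomal proteins. The camera adjusted p values were then 0.0233, 0.0197, 0.0148 and 0.0233, and with an estimated correlation adjusted p was 0.273, 0.273, 0.403 and 0.617. Wild type 1 exceeded the other controls in these lists by medians of 0.62, 0.43, 0.69 and 0.25. Without that array Slc16a1 differed by 2.62 (adjusted p 0.00317) and Atp5o by 1.62 (0.00635).

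Of 24 p53 target and checkpoint genes 1 fell, Fas, with 2 lower and 1 higher adjusted over the list alone, a median of 0.12 and a camera adjusted p of 0.569. The counts without wild type 1 were 3 higher and 5 lower. Of 22 BCL2 family and apoptosis genes 0 passed, with 2 lower adjusted over the list alone, 2 lower without wild type 1, a median of 0.0048 and a camera adjusted p of 0.245. Cflar, a regulator of death receptor signalling, differed by -1.08 (adjusted p 0.0852). In 9 lists that camera did not call, the median, the mean and the direction of the test were not all of 1 sign. These were DNA replication, mitosis, DNA damage repair, p53 target, BCL2 family, marginal zone, T cell, stromal and sex-linked genes. Camera compares a list with all other genes, whose features had a median shift of 0.08.

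Markers of other cell types moved unevenly. Over markers whose mean on all 8 arrays lay above background, a selection made after the data were seen, medians were -1.02 for 23 macrophage markers, -1.64 for 6 neutrophil and mast cell markers, -0.66 for 9 erythroid markers, -0.29 for 8 dendritic cell markers, -0.16 for 8 NK cell markers and 0.15 for 13 T cell markers. Monocyte and macrophage markers gave 8 falls and 0 rises among 27, with a median of -0.87 (camera adjusted p 5.52e-11; adjusted p 0.119 with an estimated correlation). Mpeg1, a pore-forming protein of macrophages, was 2.92-fold lower, Fcgr1, the high-affinity IgG receptor, 2.91-fold lower and the complement gene C1qa 2.71-fold lower. Wild type 1 lay within the other controls for Mpeg1, at 13.67. In this list 16 fell and 1 rose adjusted over the list alone, and without wild type 1 the counts were 8 lower and 1 higher. Neutrophil and mast cell markers gave 1 fall among 18, S100a8 at 5.23-fold, with a median of -0.46 (camera adjusted p 9.43e-06; adjusted p 0.119 with an estimated correlation), 7 lower adjusted over the list alone and 5 lower without wild type 1. Dendritic cell markers gave 1 fall among 15, Irf8, a transcription factor that B cells also use, at 4.17-fold, with a median of -0.14 (camera adjusted p 0.0218; adjusted p 0.119 with an estimated correlation). In this list 3 fell adjusted over the list alone, and without wild type 1 there were 2 lower and a camera adjusted p of 0.0578. The dendritic cell call also ended without lymphoma 1 (camera adjusted p 0.0706), without the dimmer 50% of features (0.148) and within slide 2 alone (0.258).

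T cell markers gave 1 rise and 1 fall among 21, also adjusted over the list alone. Cd2, an adhesion molecule of lymphocytes, rose 3.70-fold and Cd6 was 2.31-fold lower. Cd6 differed by -0.45 (adjusted p 0.326) with the mean of its features and by -0.87 (0.127) within slide 2 alone. Cd2 did not pass with the values as deposited (adjusted p 0.0574), scaling to the median (0.0572) or the floor (0.0505). The median of the list was -0.11, the mean 0.06 and the camera adjusted p 0.331, and without wild type 1 the counts were 2 higher and 3 lower. None of 17 NK cell markers passed, with 1 higher and 3 lower adjusted over the list alone and a median of -0.15 (camera adjusted p 0.165). Tbx21, the transcription factor T-bet, differed by -1.76 (adjusted p 0.094), and 2 were lower without wild type 1. Of 19 erythroid markers 0 passed, with 1 higher and 3 lower adjusted over the list alone, a median of -0.10 (camera adjusted p 0.0817) and 4 lower without wild type 1. Car2, a carbonic anhydrase, differed by -1.70 (adjusted p 0.0709). None of 14 platelet and megakaryocyte markers passed in either adjustment, with a median of -0.07 (camera adjusted p 0.194). Nfe2, a transcription factor, differed by -0.90 (adjusted p 0.265), and 1 was lower without wild type 1. None of 25 stromal and endothelial markers passed in either adjustment, with a median of 0.02 (camera adjusted p 0.346), 14 of them at background on all arrays of both groups. Those 7 with a mean over all 8 arrays above background had a median of -0.44, with 5 below 0. Sparc, a matrix protein, differed by 1.52 (adjusted p 0.396), and 1 was lower without wild type 1. The 4 sex-linked genes had no call in any of these counts, with a camera adjusted p of 0.793. Xist was 13.07 in wild type 2 and 13.47 in lymphoma 4 and near background on the other arrays, so each group held 1 array with a high Xist signal.

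**Figure D3:**
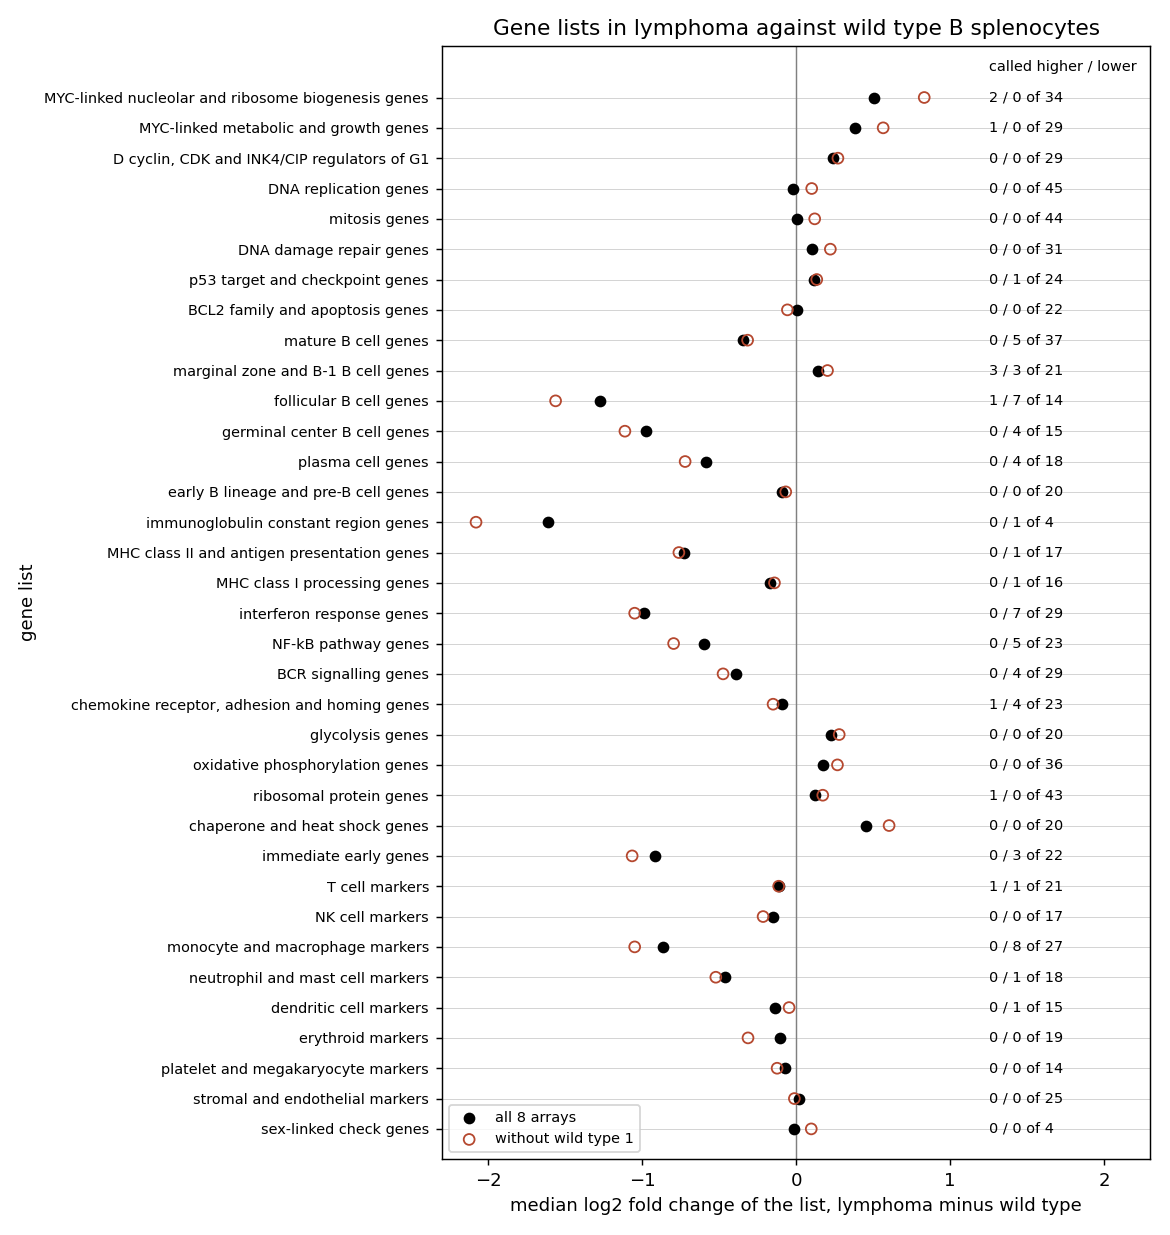
Median log2 fold change, lymphoma minus wild type, of the 35 gene lists, with all 8 arrays as filled points and without wild type 1 as open circles. Numbers give the members called higher and lower, and the members measured, with all 8 arrays. Interferon response genes lie at -0.99 and MYC-linked nucleolar and ribosome biogenesis genes at 0.51.

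In all, camera with its preset correlation called 16 of the 35 lists, 21 without wild type 1, and 0 were called with all 8 arrays with an estimated correlation, where the smallest adjusted p was 0.119. An estimated correlation called 7 lists once wild type 1 was left out, the MYC-linked nucleolar, follicular, germinal center, interferon response, NF-kB, BCR signalling and immediate early lists. That array was singled out after it was seen to lie near the lymphomas, so these calls are no separate support. Fry, which asks whether the genes of a list move on balance 1 way, called 14. Both MYC-linked lists, with fry adjusted p values of 0.166 and 0.253, were called by camera and not by fry. Several lists not called in the main fit passed in camera within 1 slide and not within the other. Some of them passed in other settings too. MHC class I processing genes were lower within slide 1 alone (adjusted p 0.0036, and 0.837 within slide 2). They were lower as well with all 8 arrays and the brightest feature away from the ceiling (0.0161). Within slide 2 alone the G1 (adjusted p 0.00674), glycolysis (0.0304), oxidative phosphorylation (2.87e-04), ribosomal protein (2.88e-04) and chaperone (0.0121) lists were higher and erythroid markers lower (0.00436), where slide 1 gave at least 0.161. Quantile normalization called the same 5 lists higher (adjusted p 0.0314 to 0.0421). Without lymphoma 2 the G1 (0.049) and oxidative phosphorylation (0.0367) lists were called higher too. Erythroid markers also passed as lower without wild type 1 (0.00406) or lymphoma 1 (0.0278) and with the mean of all features of a gene (0.00741). NK cell markers passed as lower without wild type 1 (0.0292) or lymphoma 3 (0.039).

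The lymphomas resembled one another more than the controls did. The root mean square log2 distance of an array from the mean of the other 3 arrays of its group was 0.492 ± 0.004 in lymphoma and 0.639 ± 0.110 in wild type (mean ± SD, n = 4), a difference of -0.147. A two-sided exact permutation test over these distances gave p = 0.0286, the smallest that 4 against 4 arrays can give. Each array enters the means from which the others of its group are measured, so 1 or 2 deviant controls raise all 4 control distances. The distances are therefore not independent, and the p does not measure a difference in spread between mice. Wild type 3 and 4 correlated at 0.971 across features, within the range of 0.963 to 0.974 between lymphomas. The distance was 0.712 for wild type 1, 0.754 for wild type 2, 0.550 for wild type 3 and 0.540 for wild type 4. Leaving out a lymphoma array, which leaves means over 2 other arrays in that group, gave exact p values of 0.171 without lymphoma 1, 0.2 without lymphoma 2, 0.2 without lymphoma 3 and 0.171 without lymphoma 4. The differences were then -0.120, -0.116, -0.117 and -0.120. Leaving out a control likewise leaves means over 2 arrays in the wild type group, which by itself raises the distances there and widens the difference. Without wild type 1 the difference was -0.149 (exact p 0.0286), without wild type 2 it shrank to -0.123 with the same p, and it was -0.236 without wild type 3 and -0.241 without wild type 4.

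Between the slides, with the group in the model, 2 of 33709 features passed, both higher on slide 2, and 3725 features had an unadjusted p under 0.05 in limma.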

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

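The tests on wild type 1, on single lists over other splits and on the markers of other cell types were chosen only after the results were seen, and the other counts over splits of the arrays were planned. In 27 of 226 groups of 4 arrays, 1 array lay far from the other 3, where its gap to the nearest array made up more of the range than a Dixon test at the 95% level allows. Chance marks about 1 in 20 groups, or 11.3 of 226, and genes of 1 list are not independent. Of the 27 marks, 14 came from wild type 1 and 2 from wild type 2. The value given below for each is that gap as a share of the range.

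Wild type 1 was high for Apobec2 (0.902), Zbtb32 (0.926), Eml1 (0.930), Nid1 (0.8292), Ankrd13b (0.851) and Cd2 (0.940), and low for Icosl (0.918), Fas (0.953) and Irf8 (0.876). It was also high in the mean of the MYC-linked nucleolar and ribosome biogenesis genes (0.898) and of the MYC-linked metabolic genes (0.8291). It was low in the mean of the germinal center genes (0.831), the immunoglobulin constant region list with Jchain (0.915) and the immediate early genes (0.953). Wild type 2 was high for Xist (0.854). For Ihh it stood apart (0.861) among values all at background, so this gap shows no high signal.

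Among the lymphomas, lymphoma 1 was low for Zbtb32 (0.838). Lymphoma 2 was low for Nid1 (0.901), E2f6 (0.908) and Sparc (0.902) and high for Cflar (0.905). Lymphoma 3 was high for Hspb1 (0.883) and Oasl1 (0.967). Lymphoma 4 was low for Tppp (0.929) and Tap1 (0.918), high for Xist (0.918) and low in the mean of the sex-linked genes (0.861). Of 11511 features without a listed gene, which no comparison above uses, 27 were higher and 66 lower in lymphoma.

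With genes chosen from wild type 2 to 4 and 3 lymphomas, the lymphoma left out lay at a median position of 0.884 to 1.051 on a scale from wild type (0) to lymphoma (1), and wild type 1 at 0.704 to 0.759, a gap of at least 0.125. For genes lower in lymphoma wild type 1 lay at 0.595 to 0.627 and the lymphomas at 0.869 to 1.028. For these genes the values argue against lymphoma RNA alone under a wild type label. For genes higher in lymphoma wild type 1 lay at 0.885 to 0.909 and the lymphomas at 0.892 to 1.085. Those ranges overlap, so the genes higher in lymphoma do not decide it. A poor array unrelated to the groups is argued against by the correlation of its departure with the lymphoma change, measured against different controls, which was at least 0.434 across genes in 6 choices. A uniform share of lymphoma RNA mixed into wild type RNA cannot be told apart from other causes, since the share needed for genes lower minus that for genes higher in lymphoma was -9.11 percentage points, and 30.7 in genes whose groups lie far apart. A difference of that mouse stays open and was not tested.

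Macrophage markers above background in the controls had a median of -1.08 and T cell markers of -0.113. The difference was -0.967 (permutation p 0.0015 over genes, which are not independent). It does not decide on a loss of all other cell types by the same share. Lymphoma cells could themselves express genes of the T cell list, which holds Cd2, 3.70-fold higher, and Cd5, a surface marker of mantle cell lymphoma. A loss of several cell types stays open as well, since neutrophil (-1.64) and erythroid (-1.02) markers were lower too. Markers chosen by their level in the controls lean toward falls. Wild type 1 does not decide the macrophage fall, since the median of all macrophage markers without it was -1.05. Macrophages also express interferon response, NF-kB and MHC class II genes, so part of the falls in those lists could lie in these cells, which was not tested.

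For the 557 features and the 398 genes the splits argue against chance. No other of the 35 splits of the arrays into 4 and 4 gave more than 5 features or 2 genes, so that 1 split, the real one, reached the count. A rank among 35 splits can be no rarer than 1 in 35. Every other split mixes the groups, so a real group difference widens the spread within them and lowers their counts. The splits also cannot tell lymphoma from anything else that goes with the group. Without wild type 1 the real split gave 1556 genes and the highest other split 3. That array was singled out after it was seen to lie near the lymphomas, so this rank does not decide on chance. For the 16 lists chance is not excluded, since 7 of the 35 splits called as many and the highest other called 23. That split put wild type 1 with lymphoma 1, 3 and 4, and the reason for its count was not tested. Taken singly, the mature B cell, follicular, germinal center, MHC class II, interferon response and immediate early lists reached their median and their camera p in the real split alone. Counting the real split among the 35, a p as small came in 6 and 11 for the MYC-linked nucleolar and metabolic lists, 4 each for the macrophage and dendritic cell lists, 3 for the plasma cell list and 2 each for the immunoglobulin, NF-kB and neutrophil lists. The BCR signalling and homing lists reached their p in the real split alone, but a median as large came in 2 and 26. For the 2 features between the slides, the 18 splits are too few for a share under 0.05, and the highest other gave 3, with 4 splits of at least 2.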

How the results depend on the processing

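The use of all features of the table and of the brightest feature away from the ceiling was chosen only after the data were seen. No called list changed direction in any setting. Of the 398 called genes, all that were measured kept their direction in every setting but 1. With the mean of all features of a gene Atl3, chosen after its values were seen, was at 0.0261 (adjusted p 0.957). The named genes past the threshold numbered 54, and their highest adjusted p ranged from 0.0182 with array weights to 0.708 within slide 1 alone. The features called were 2128 with array weights, 0 within slide 1 alone, 1949 within slide 2 alone, 1 in a plain t-test and between 84 and 2317 leaving out 1 array. The genes called were 1441 with array weights, 0 within slide 1, 1288 within slide 2 and between 74 and 1556 leaving out 1 array. Other settings gave 506 to 713 features and 367 to 526 genes. Lists called with all 8 arrays and an estimated correlation were 0, and those by fry or by camera with its preset correlation were 14 to 22 over all settings. The spread difference ranged from -0.241 to -0.116 leaving out 1 array. The slide term gave 1 feature with quantile normalization and 1 without the dimmer 50% of features. Fewer arrays leave less precision, and beyond that the cause was not tested. About 50% of listed features lay near background, where changes are compressed, and Myc and ribosomal protein genes near the ceiling.

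Wild type and lymphoma arrays share replicate numbers 1 to 4. The replicate number as a block gave 713 features and 526 genes. Correlations of the residuals with the same number were 0.189, -0.041, 0.135 and -0.010. The values of 0.189 and 0.135 were the highest among all pairs of a control and a lymphoma. Not every array correlated best with its own number, so whether the numbers pair the arrays stays open.

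The results below did not pass with all 8 arrays, and the cause of each change of direction was not tested. For lists the direction is relative to all other genes, and the value is the mean log2 shift. With quantile normalization the opposite direction was given by Cdkn2a (-0.00127), DNA replication genes (0.0395), mitosis genes (0.00608), DNA damage repair genes (0.0522), p53 target and checkpoint genes (-0.00254), sex-linked check genes (0.00233). With the values as deposited the opposite direction was given by Ccnd1 (-0.024), Cdkn2a (-0.035). Without the dimmer 50% of features the opposite direction was given by DNA replication genes (0.0215), DNA damage repair genes (0.0241), p53 target and checkpoint genes (0.00703), T cell markers (0.193), sex-linked check genes (0.00361). With array weights the opposite direction was given by Ccnd1 (-0.0307), Mki67 (0.346), Sox11 (0.0247). With the replicate number as a block the opposite direction was given by DNA damage repair genes (0.0409). Within slide 1 alone the opposite direction was given by Ccnd2 (-0.257), Ccnd3 (0.00892), Cd5 (-1.186), Cdkn2a (-0.344), Myc (-0.0623), Nfe2 (0.0871), Xist (-3.306), D cyclin, CDK and INK4/CIP regulators of G1 (0.0647), oxidative phosphorylation genes (-0.043), ribosomal protein genes (0.0654), chaperone and heat shock genes (0.055), erythroid markers (0.0508), sex-linked check genes (0.258). Within slide 2 alone the opposite direction was given by Ccnd1 (-0.252), Mki67 (0.484), Sox11 (0.192), DNA replication genes (0.241), mitosis genes (0.287), DNA damage repair genes (0.0738), p53 target and checkpoint genes (0.0678), marginal zone and B-1 B cell genes (0.0212), MHC class I processing genes (0.0635). With the mean of all features of a gene the opposite direction was given by Bcl2 (0.0300), Sox11 (0.10), Rag2 (0.00567), DNA damage repair genes (0.0841), sex-linked check genes (0.177). Leaving out 1 array at a time, results that changed direction ranged as follows: Ccnd1 -0.244 to 0.264, Mki67 -0.382 to 0.175, Xist -1.358 to 1.905, DNA replication genes -0.0691 to 0.126, mitosis genes -0.132 to 0.138, DNA damage repair genes -0.0748 to 0.161, Sox11 -0.314 to 0.0111, p53 target and checkpoint genes -0.0576 to 0.078, Cdkn2a -0.231 to 0.295, Cd5 -0.092 to 0.458, sex-linked check genes -0.115 to 0.200.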

Other observations

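The genes named in the first 2 paragraphs here were chosen after their values were seen. Beyond the lists, S100a6, Krt18, Ahnak, Tubb6 and Capn2 were higher in lymphoma, and no test of them as a group was made. S100a6, a small calcium-binding protein, was at 12.70 ± 1.68 in wild type and 15.86 ± 0.13 in lymphoma (mean log2 intensity ± SD, n = 4; adjusted p 0.0334 in limma), near the ceiling on 3 lymphoma arrays. Krt18, a keratin of epithelial cells at background on 3 control arrays, was 11.4-fold higher (adjusted p 0.0265), Ahnak, a very large scaffold protein, 14.0-fold (adjusted p 0.0328), Tubb6, a beta tubulin, 7.18-fold (adjusted p 0.0379) and Capn2, a calcium-activated protease, 5.48-fold (adjusted p 0.0288). Lmna, which encodes lamin A, differed by 3.29 (adjusted p 0.0615), and without wild type 1 by 4.32 with an adjusted p of 1.12e-05. Leaving out wild type 1 raised the difference to 4.01 for S100a6, 4.64 for Ahnak, 3.62 for Tubb6 and 3.05 for Capn2 on the log2 scale, and Krt18 was then at background in every control. For S100a6 and Lmna wild type 1 stood at 15.21 and 15.31, against means of 11.86 and 11.17 in the other controls. Cd8b1, a T cell coreceptor chain, differed by 2.67 (adjusted p 0.188), with 13.27 in wild type 1 and a mean of 8.42 in the other controls.

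Of 19 variable segments of the immunoglobulin genes with a feature, 6 were called lower and 0 higher, and 17 had a negative difference, with a median of -1.71. Ighv14-2 differed by -2.65 (adjusted p 0.00622). Without wild type 1, 12 were lower and 0 higher. Iglv1, near the ceiling at 15.75 in wild type and 15.87 in lymphoma, differed by 0.12 (adjusted p 0.869). Wild type 1 was also low in Lyve1 and Nr2f2. Lyve1, a hyaluronan receptor of lymphatic and sinus endothelium, was at background in lymphoma and at least 7.16-fold lower there (adjusted p 0.0467), with 7.16 in wild type 1 against 11.07 in the other controls and 6.62 in lymphoma. Nr2f2, a transcription factor of venous and lymphatic endothelium, was 6.37 in wild type 1, 10.25 in the other controls and 6.58 in lymphoma, and its difference did not pass with all 8 arrays (adjusted p 0.103).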
